A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

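The series holds 18 samples of *S. cerevisiae* cells carrying human MeCP2 or a control plasmid. The 6 RNA libraries came with tables; the 12 ChIP and input samples came without files and were not analysed here. Per the labels' protocols, cells of an S288C strain of mating type a received 1 µM estradiol for 4 h, then 4-thiouracil for 8 min, and RNA was treated with iodoacetamide before a stranded polyA library was made. Per the submitters' processing notes, reads were trimmed with fastp, reports were gathered with MultiQC and conversions were counted with SLAM-DUNK on sacCer3; the notes give no versions of fastp or MultiQC.

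The deposited tables hold, per 3' interval and per the file headers, counts of reads, of reads with T>C conversions and of multimapping reads, and counts of covered T positions and of conversions on them. They also hold a conversion rate, a fraction that the authors computed as conversions over covered T positions, and a CPM column in which the authors scaled reads to the read total of the library. That column shows that the intervals took 1.22% to 1.62% of the reads of each library. The 5529 intervals have a median length of 120 bases, and 397 have length 0. On the same strand, 261 overlap another gene's coding span or the 100 bases upstream of it. On the opposite strand, 1756 overlap a coding span or an interval, which the stranded counting separates. Their starts matched coding ends for 5524 of 5525 genes compared, and 5528 locus tags matched the gene table used for names.

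Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM, 1 quasi-likelihood fit with a coefficient for each of the 3 groups of 2 libraries (3 residual degrees of freedom), and Benjamini-Hochberg adjustment at 0.05. CPM values in the text are relative to these TMM-scaled interval totals, and every adjusted p of a gene is from this test. T>C reads were scaled on the total reads, so that a change in their overall share is kept. A further fit set T>C reads against other reads of the same interval. Standard errors were taken from the fitted change and its F statistic. Shares of T>C reads were compared with exact permutation tests, and single shares carry 95% Wilson intervals.

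Of the gene lists written by hand, those with at least 5 tested members (23 for total reads, 4 for T>C reads) were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Camera was repeated with an estimated correlation, and fry was also run. Camera asks whether members changed more than other genes, and fry whether they changed at all. With an estimated correlation 0 list calls held in all 3 comparisons and both kinds of reads. The cytosolic chaperone list also holds *HSP78*, a mitochondrial chaperone gene, and the coactivator gene *MBF1*.

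Genes were named by a rule: among genes past adjusted p 0.05 whose CPM values did not overlap between the 4 libraries compared, with a mean of at least 20 reads per library in the higher group, the 8 highest and the 8 lowest changes. Up to 4 members with the smallest p were named for each list described, and the strain and plasmid markers always. Genes outside this rule are said to be chosen after their values were seen. Where a group had 1 to 3 counts, the ratio of pooled counts is given with an exact counting interval. The tests, lists, naming rule and alternative settings were fixed before the data were examined.

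These settings were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 50 counts per library, fits of the 4 libraries compared, a replicate block, scaling on the T>C reads, conversions in place of T>C reads, and leaving out each library in turn. After seeing the data, scaling on the library sizes behind the deposited CPM and leaving out intervals with same-strand overlaps were added. Shared controls were simulated with 100 draws of unchanged groups.

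The scripts were tested on simulated data, with 10 draws of counts from the vector means and the sizes of the 6 libraries. Changes were put into the wild-type libraries, up and down equally often for total and T>C reads. The draws thus did not cover the common fall of T>C reads in wild-type cells (median −1.11). With 200 of 2447 genes changed in total reads, 40% of 2-fold and 82.2% of 4-fold changes were recovered, and 3.65% of calls were wrong. With 60 of 263 changed in T>C reads, 26.3% and 80.7% were recovered with 2.57% of calls wrong, and for T>C against other reads 16% and 60.7% with 5.74% wrong. A list of 20 genes at 1.5-fold had an unadjusted camera p under 0.05 in 10 of 10 draws for total reads and 9 of 10 for T>C reads. Genes were drawn independently, so these draws cover neither correlation within a list nor the adjustment over lists. Other computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.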

Results

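RNA was measured in 6 SLAM-seq libraries of *Saccharomyces cerevisiae* cells, 2 from cells with the empty vector pRS416, 2 from cells expressing human wild-type MeCP2 and 2 from cells expressing the T158M mutant. MeCP2 is a chromosomal protein that binds methylated CpG in mammals, and T158M is a mutation of its methyl-binding domain. SLAM-seq marks RNA made during a short pulse of 4-thiouracil. Iodoacetamide turns the label into T-to-C conversions, so reads with such conversions (T>C reads) are taken as newly made RNA. Total reads come from all polyadenylated RNA. The deposited tables counted reads in 5529 intervals at gene 3' ends on the sacCer3 genome. The vector libraries held 289253 and 417763 interval reads, the wild-type libraries 294709 and 318476, and the T158M libraries 297463 and 447107. Of these, 11233 and 17149 were T>C reads in the vector libraries, 5726 and 6301 in the wild-type libraries, and 8012 and 13256 in the T158M libraries. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. Counting intervals cover counting error only, since reads had no molecular identifiers.

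The question set by the title of the series was whether MeCP2 inhibits transcription in yeast. The 12 ChIP and input samples came without files and were not analysed here. MeCP2 itself is not in the tables. Vector cells carried only pRS416, so comparisons with them include everything else that the MeCP2 plasmids encode, whereas wild-type against T158M compares matched plasmids. The strain and plasmid marker genes had few reads: the *HIS3* interval held 3 and 8 reads in the vector libraries, 8 and 11 in the wild-type libraries, and 4 and 7 in the T158M libraries. *LYS2* held 0 to 11 reads per library, *TRP1* held 2 reads in T158M replicate 2 and 0 in the other libraries, and *URA3* and *LEU2* were not among the intervals.

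The share of reads carrying T>C conversions was lowest in the cells expressing wild-type MeCP2. It was 3.99% ± 0.157 (SD, n = 2) in vector cells, 2.83% ± 0.192 (SD, n = 2) in T158M cells and 1.96% ± 0.0251 (SD, n = 2) in wild-type cells. The wild-type share was 0.491 of the vector share and 0.693 of the T158M share, and the T158M share was 0.708 of the vector share. Both libraries of each group lay apart from both libraries of the others, but the two-sided exact permutation test of each pair of groups gave p = 0.333, the smallest that 2 libraries against 2 allow. T>C reads carried 1.57 ± 0.0272 conversions in vector cells, 1.63 ± 0.00682 in wild-type cells and 1.56 ± 0.000304 in T158M cells (SD, n = 2 each). Ribosomal protein genes took 15.9% ± 0.243 of the reads in vector cells, 13.0% ± 0.347 in wild-type cells and 14.9% ± 0.883 in T158M cells (SD, n = 2 each).

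**Figure D1:**
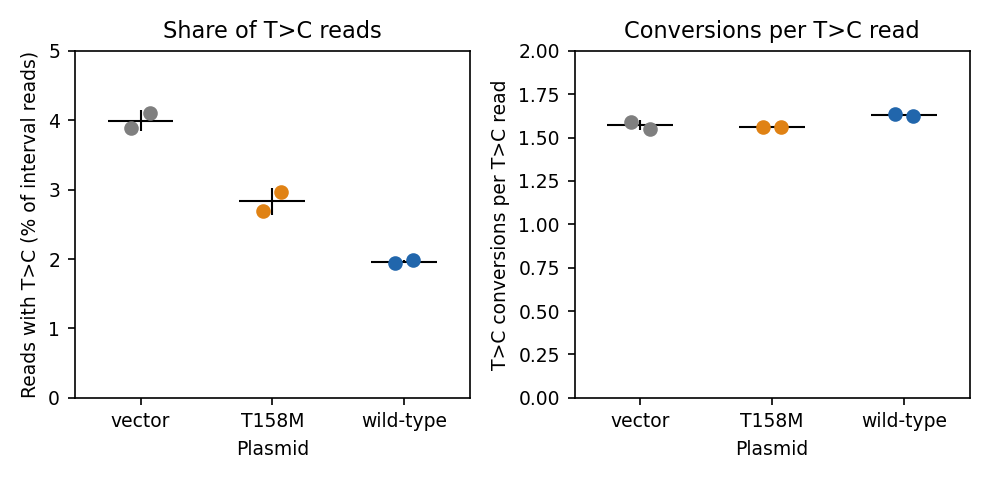
Percent of interval reads with T>C conversions (left) and conversions per T>C read (right) by plasmid; points are libraries, horizontal lines group means and vertical lines 1 SD (n = 2). The T>C share was 3.99% in vector, 2.83% in T158M and 1.96% in wild-type cells, while conversions per T>C read lay between 1.55 and 1.63.

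Scaled on total reads, T>C reads of most measured genes were fewer in wild-type MeCP2 cells than in vector cells. *NCE102*, which encodes a plasma membrane protein of eisosomes, fell by 3.51 ± 0.41 on the log2 scale (SE, n = 2 per group; adjusted p = 1.6e-04). *YGP1*, a secreted glycoprotein made under nutrient limitation, fell by 3.18 ± 0.50, *ROQ1*, a regulator of stress-induced protein degradation, by 2.89 ± 0.30, and *ACP1*, the mitochondrial acyl carrier protein, by 3.60 ± 0.56. *SWM1*, a subunit of the anaphase-promoting complex, fell by 3.16 ± 0.64. Few T>C reads remained for 3 further genes. *TMA10* had 1 T>C read in wild-type cells and 41 in vector cells, a ratio of 0.0266 (95% counting interval 0.000658 to 0.157). *RTC3* had 2 and 52, a ratio of 0.0420 (0.00495 to 0.159), and *PNC1*, the nicotinamidase of NAD salvage, had 3 and 44, a ratio of 0.0744 (0.0148 to 0.232). Of 263 genes tested, 108 were lower and 0 higher past adjusted p 0.05 in edgeR, 140 passed at an unadjusted p under 0.05, and DESeq2 called 86. The median change over all tested genes was −1.11, and 234 of the 263 lay below 0. When libraries were scaled on their T>C reads alone, the median moved to −0.02 and 22 genes passed, 10 higher and 12 lower, in place of 0 and 108. Relative to that shift, *NCE102* still fell by 2.41, *ROQ1* by 1.80, *YGP1* by 2.10, *ACP1* by 2.52, *TMA10* by 3.95 and *RTC3* by 3.43. *SWM1* (−2.07, adjusted p = 0.0595) and *PNC1* (−2.53, adjusted p = 0.0850) no longer passed. Leaving out wild-type replicate 2 moved the changes by over 1.5 times for *ACP1* (−4.49), *YGP1* (−3.92), *ROQ1* (−3.57) and *SWM1* (−2.57; −4.15 without wild-type replicate 1).

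Genes of the cytosolic chaperone list had fewer T>C reads in wild-type MeCP2 than in vector cells. Whether they fell more than other genes depended on the setting. Of 8 tested members, 7 fell, 0 rose and 1 did not pass, and 7 fell adjusted over the list alone. The Hsp90 gene *HSP82* fell by 1.74 ± 0.24, the Hsp70 gene *SSA1* by 2.05 ± 0.35, the Hsp90 regulator *HCH1* by 1.70 ± 0.29 and the coactivator gene *MBF1* by 1.49 ± 0.27 (SE, n = 2 per group). The change of *SSA1* was −2.65 without wild-type replicate 2. The list median was −1.61 (camera adjusted p = 0.0338; adjusted p = 0.358 with an estimated correlation). This list call ended without vector replicate 2 (adjusted p = 0.136) and without wild-type replicate 1 (adjusted p = 0.0832). With libraries scaled on T>C reads *SSA1* still passed (−0.94, adjusted p = 0.0402), while *HSP82* (−0.64, 0.131), *HCH1* (−0.61, 0.334) and *MBF1* (−0.39, 0.535) did not. Of 13 ribosomal protein genes tested for T>C reads 2 fell and 11 did not pass, 0 fell adjusted over the list alone, 11 lay below 0 and their median was −0.64. Camera did not pass this list (adjusted p = 0.0552, direction up, and adjusted p = 0.358 with an estimated correlation). The members that fell were *RPL8A*, by 1.65 ± 0.52, and *RPL41A*, by 0.64 ± 0.23, and both have near-identical copies between which the counting could split reads.

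In T158M cells T>C reads scaled on total reads were also fewer than in vector cells, by less in the median. *YRO2*, a plasma membrane protein gene, fell by 1.78 ± 0.25 (SE, n = 2 per group; adjusted p = 0.00625), *YGP1* by 2.39 ± 0.44 and *PNC1* by 2.96 ± 0.68. *TMA10* fell by 3.19 ± 0.83, *UBC4*, a ubiquitin-conjugating enzyme, by 2.81 ± 0.63, *RTC3* by 2.46 ± 0.59 and *BMH1*, a 14-3-3 protein, by 1.69 ± 0.45. *MPM1* fell by 1.74 ± 0.46, but its interval overlaps the coding span of *YJL068C*, or the bases just upstream of it, on the same strand. In edgeR 21 of 263 genes fell and 0 rose (77 at an unadjusted p under 0.05; 13 in DESeq2), and the median was −0.56. With libraries scaled on T>C reads 0 passed in edgeR (27 at an unadjusted p under 0.05) and the median was 0.05. The count of 21 became 13 without vector replicate 2, 34 without wild-type replicate 1 and 32 without wild-type replicate 2. With vector replicate 2 left out *TMA10* no longer passed (adjusted p = 0.247), with vector replicate 1 left out *UBC4*, *RTC3* and *MPM1* did not (0.103, 0.240 and 0.295), and with T158M replicate 2 left out *BMH1* did not (0.173). The sizes for *TMA10*, *RTC3* and *PNC1* rested on single T158M libraries: without T158M replicate 2 they were −7.29, −4.35 and −4.02, and without T158M replicate 1 that of *TMA10* was −2.51.

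For T158M against vector cells, 8 genes of the cytosolic chaperone list were tested for T>C reads. Of these, 4 fell and 0 rose, and 6 fell adjusted over the list alone. *SSA1* fell by 1.48 ± 0.33, *HSP82* by 0.91 ± 0.22, the coactivator gene *MBF1* by 0.94 ± 0.25 and the Hsp70 gene *SSA2* by 1.09 ± 0.29 (SE, n = 2 per group). The list median was −0.95 (camera adjusted p = 0.00867; adjusted p = 0.288 with an estimated correlation). The list no longer passed without vector replicate 2 (adjusted p = 0.0513) or T158M replicate 2 (adjusted p = 0.0668), and without vector replicate 2 the calls of *HSP82*, *MBF1* and *SSA2* ended (adjusted p = 0.149, 0.236 and 0.149). DESeq2 called none of the 4 genes (adjusted p = 0.141 for *SSA1*, 0.0512 for *HSP82*, 0.159 for *MBF1* and 0.151 for *SSA2*). With libraries scaled on T>C reads they did not pass either (adjusted p = 0.166, 0.681, 0.681 and 0.654).

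In the plasmid-matched comparison T>C reads scaled on total reads were also fewer with wild-type MeCP2 than with T158M. *TOS6*, a cell wall protein gene, fell by 2.71 ± 0.45 (SE, n = 2 per group; adjusted p = 0.0128), *ATG41*, an autophagy gene, by 2.21 ± 0.48 and *NCE102* by 1.94 ± 0.46. *HMS2* fell by 1.93 ± 0.45, the efflux transporter gene *ATR1* by 1.89 ± 0.51, the histone H2B gene *HTB2* by 1.62 ± 0.44, *ROQ1* by 1.56 ± 0.32 and *PMP2*, a regulator of the plasma membrane proton pump, by 1.25 ± 0.31. Of 263 genes, 20 fell and 0 rose (61 at an unadjusted p under 0.05 and 14 in DESeq2), and the median was −0.57. A replicate block left 2 lower and 0 higher. With libraries scaled on T>C reads the median was −0.08 and 5 genes passed, 2 higher and 3 lower. These 5, named after their values were seen, were *RPL36B* and *ROX1* (higher) and *HSK3*, *TOS6* and *USA1* (lower). The *USA1* interval lies at the 5' end of *TSA1* and took 4.61% to 7.00% of the reads of a library. The count of 20 fell to 9 without wild-type replicate 1 and to 8 without wild-type replicate 2. Calls ended for *ATR1* and *ROQ1* without wild-type replicate 1 (adjusted p = 0.137 and 0.0984), for *HMS2*, *HTB2* and *PMP2* without wild-type replicate 2 (0.193, 0.326 and 0.276), and for *ATG41* and *NCE102* without T158M replicate 2 (0.132 and 0.190), where their changes shrank to −1.60 and −1.23. Changes grew for *HTB2* without wild-type replicate 1 (−2.34) and for *ROQ1* without wild-type replicate 2 (−2.23). Camera called 0 of the 4 lists tested (1 at an unadjusted p under 0.05; fry called 0).

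Setting T>C reads against the other reads of the same interval asked whether the T>C part of each mRNA changed. In wild-type against vector cells the T>C part was lower for 97 of 263 genes and higher for 1, with a median change of −1.17. The gene that was higher, named after its value was seen, was the ribosomal protein gene *RPL4A* (1.95 ± 0.69), which has a near-identical copy. With each kind of read scaled on its own, 15 passed, 4 higher and 11 lower, and the median was −0.14. The count of 98 became 47 without vector replicate 1, 34 without vector replicate 2 and 39 without wild-type replicate 2. In T158M against vector cells 0 of 263 passed in edgeR (62 at an unadjusted p under 0.05; no other tool was run), with a median of −0.61. That count became 4 without wild-type replicate 1 and 1 without wild-type replicate 2, and under the filter of 50 counts 14 of 20 genes passed, all lower. In wild-type against T158M cells 15 were lower and 0 higher (63 at an unadjusted p under 0.05), with a median of −0.55. With each kind of read scaled on its own 6 were lower and 0 higher. The count of 15 became 0 without vector replicate 1, 7 without vector replicate 2, 6 without wild-type replicate 2 and 0 without T158M replicate 2.

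Several heat-shock genes were far higher in total RNA of wild-type MeCP2 cells than of vector cells. *HSP12* (YFL014W, chromosome VI, 107586 to 107770, plus strand), which encodes a small membrane-associated stress protein, rose from 1111 ± 14.4 to 21757 ± 400 CPM (SD, n = 2 each), a log2 change of 4.29 ± 0.20. The small heat-shock protein gene *HSP26* (YBR072W, chromosome II, 382675 to 382840, plus strand) rose by 3.97 ± 0.21, the Hsp70 genes *SSA3* and *SSA4* by 3.79 ± 0.59 and 3.10 ± 0.22, and the Hsp40 gene *SIS1* by 3.38 ± 0.48. *PRM1*, needed for membrane fusion in mating (YNL279W, chromosome XIV, 112903 to 113154, plus strand), rose by 5.78 ± 0.40, with 526 reads in wild-type and 10 in vector cells; its size depended on the control, at 7.28 without vector replicate 1 and 4.80 without vector replicate 2. *DSE4*, a glucanase of daughter cell separation, rose by 3.94 ± 0.46, *NCA3* by 3.88 ± 0.44 and *YNR064C* by 3.70 ± 0.46. *CYS4*, the cystathionine beta-synthase gene (YGR155W, chromosome VII, 800067 to 800204, plus strand), fell by 2.42 ± 0.34, *YRO2* by 2.22 ± 0.21 and the chromatin protein gene *NHP6B* by 2.42 ± 0.45. *MDG1* fell by 3.32 ± 0.73, *COA4*, a cytochrome oxidase assembly factor, by 2.95 ± 0.62, *AYR1* by 2.79 ± 0.68, the glucose transporter gene *HXT7* by 2.28 ± 0.50 and the fatty acid activation gene *FAA1* by 2.14 ± 0.74. *HXT7* has a near-identical copy between which reads could be split. In edgeR 436 of 2447 genes passed, 210 higher and 226 lower. When only the 4 libraries compared were fitted, 723 passed, 355 higher and 368 lower.

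Leaving out any 1 library moved this count of 436 by over 1.5 times. It was 164 without vector replicate 1, 68 without vector replicate 2, 237 without wild-type replicate 1, 183 without wild-type replicate 2, 703 without T158M replicate 1 and 698 without T158M replicate 2. Of the 436 genes, 58 were called in all of these fits, 38 higher and 20 lower. Scaling on the library sizes behind the deposited CPM, chosen after seeing the data, left 112 genes, 76 higher and 36 lower, in place of 210 and 226. Without vector replicate 2 the calls ended for *MDG1* (adjusted p = 0.0745), *COA4* (0.131, change −2.35), *AYR1* (0.181), *HXT7* (0.146) and *FAA1* (0.311). Sizes of genes with few reads also moved by over 1.5 times with 1 library. Without wild-type replicates 1 and 2 in turn, the change of *AYR1* was −1.86 and −8.31 and that of *FAA1* −4.55 and −1.27, and without wild-type replicate 1 that of *NHP6B* was −3.28. Without vector replicate 2 the rise was 4.87 for *DSE4*, 4.01 for *SIS1* and 3.08 for *SSA3*, which rose by 4.57 without vector replicate 1.

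Several gene groups fixed beforehand differed in total RNA between wild-type MeCP2 and vector cells. Genes of the mating program of a cells rose: of 13 tested, 6 rose, 0 fell and 7 did not pass, and 7 rose adjusted over the list alone. Their examples were *PRM1*, the agglutinin gene *AGA2* (1.46 ± 0.22), the kinesin partner gene *CIK1* (1.92 ± 0.35) and the pheromone receptor gene *STE2* (0.89 ± 0.22). The list median was 0.89 (camera adjusted p = 6.5e-05; adjusted p = 0.390 with an estimated correlation). Of 130 ribosomal protein genes 33 fell, 0 rose and 97 did not pass, and 39 fell adjusted over the list alone, with a median of −0.50 (camera adjusted p = 2.7e-10; adjusted p = 0.518 with an estimated correlation). *RPL38* fell by 1.89 ± 0.26, *RPL13A* by 1.25 ± 0.23, *RPS27A* by 1.10 ± 0.21 and *RPS26B* by 1.32 ± 0.25, and copies of such genes could share reads. Of 33 respiration genes 10 fell and 0 rose, 11 fell adjusted over the list alone, and the median was −0.53 (camera adjusted p = 0.00142; adjusted p = 0.639 with an estimated correlation). The complex III gene *QCR7* fell by 1.17 ± 0.21 and the ATP synthase genes *ATP7*, *ATP14* and *ATP4* by 1.42 ± 0.30, 1.19 ± 0.25 and 1.01 ± 0.21. Without vector replicate 2 the calls of *STE2* (adjusted p = 0.202), *RPS27A* (0.0610), *RPS26B* (0.0694), *ATP7* (0.0584), *ATP14* (0.100) and *ATP4* (0.112) ended. Fry passed the mating list (adjusted p = 0.0391) but not the ribosomal protein (0.0552) and respiration lists (0.0823).

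Glycolysis, histone and sulfur assimilation genes were also lower in total RNA of wild-type MeCP2 cells than of vector cells. Of 14 glycolysis genes 6 fell and 0 rose, 7 fell adjusted over the list alone, and the median was −0.71 (camera adjusted p = 0.00142; adjusted p = 0.390 with an estimated correlation). The enolase gene *ENO1* fell by 1.59 ± 0.33, the phosphofructokinase gene *PFK1* by 1.10 ± 0.24, *TDH2* by 1.00 ± 0.22 and the hexokinase gene *HXK2* by 1.04 ± 0.24. Of 8 histone genes 4 fell and 0 rose, 5 fell adjusted over the list alone, and the median was −0.76 (camera adjusted p = 0.00497; adjusted p = 0.518 with an estimated correlation). They were *HTA2* (−1.09 ± 0.22), *HTA1* (−0.87 ± 0.22), *HHF1* (−1.31 ± 0.34) and *HTB2* (−0.65 ± 0.20), and each has a near-identical copy. Of 11 sulfur assimilation genes 5 fell and 0 rose, while 6 fell and 1 rose adjusted over the list alone, with a median of −0.81 (camera adjusted p = 0.0192; adjusted p = 0.639 with an estimated correlation). Besides *CYS4*, the methionine synthase gene *MET6* fell by 1.07 ± 0.25 and the S-adenosylmethionine synthetase genes *SAM1* and *SAM2* by 0.81 ± 0.22 and 0.89 ± 0.20. The sulfur list did not pass without vector replicate 2 (adjusted p = 0.0509) or wild-type replicate 1 (adjusted p = 0.118). Fry passed the glycolysis list (adjusted p = 0.0349) but not the histone (0.0612) and sulfur lists (0.0823). Single calls ended for *TDH2* and *HXK2* without vector replicate 1 (adjusted p = 0.118 and 0.0881) and for *ENO1*, *HHF1* and *MET6* without vector replicate 2 (0.0531, 0.255 and 0.0826). They ended for *SAM2* without wild-type replicate 1 (0.162), and for *PFK1*, *HTA2*, *HTA1*, *HTB2* and *SAM1* without wild-type replicate 2 (0.106, 0.101, 0.247, 0.217 and 0.192).

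Stress genes as groups went both ways in wild-type MeCP2 against vector cells. Of 26 general stress response genes 7 rose and 6 fell, with the same counts adjusted over the list alone, and the median was 0.22 (camera adjusted p = 0.0788; adjusted p = 0.694 with an estimated correlation). *HSP12*, *FMP16* (462 reads in wild-type and 64 in vector cells) and *MSC1* (2.82 ± 0.39; 3.42 without vector replicate 2) rose, and *PNC1* fell by 1.43 ± 0.23. This list passed without vector replicate 2 (adjusted p = 0.0118) and without wild-type replicate 2 (adjusted p = 0.0109). Of 23 genes of the cytosolic chaperone list 6 rose and 5 fell, and 7 rose and 7 fell adjusted over the list alone. This list did not pass (camera adjusted p = 0.159, and adjusted p = 0.639 with an estimated correlation). Its median was −0.07 and its mean 0.37.

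T158M cells differed less from vector cells in total RNA, and several stress genes were lower in them. *PRM1* rose by 4.60 ± 0.42 (SE, n = 2 per group; adjusted p = 3.3e-07; 6.11 without vector replicate 1 and 3.63 without vector replicate 2), *CIK1* by 2.05 ± 0.34, *YDR124W* by 2.21 ± 0.36, *YCR102C* by 1.72 ± 0.26, *VHR2* by 1.31 ± 0.28 and *PRY2*, a sterol-binding protein gene, by 1.17 ± 0.19. *HSP12* rose by 1.44 ± 0.18, to 3013 ± 518 CPM (SD, n = 2). *YHK8* rose by 1.66 ± 0.32, but its interval overlaps the coding span of *FSH1*, or the bases just upstream of it, on the same strand. *YGP1* (YNL160W, chromosome XIV, 337610 to 337825, plus strand) fell by 1.92 ± 0.22, *YRO2* (YBR054W, chromosome II, 344136 to 344360, plus strand) by 1.79 ± 0.21, *TMA10* by 1.84 ± 0.25 and *RTC3* by 1.60 ± 0.25. *HXT7* fell by 1.76 ± 0.46, *SLX9* by 1.68 ± 0.35, the cell wall gene *SPI1* by 1.66 ± 0.36 and *MET28*, a regulator of sulfur metabolism, by 1.51 ± 0.29. In edgeR 46 of 2447 genes passed, 17 higher and 29 lower, and 307 at an unadjusted p under 0.05. When only the 4 libraries compared were fitted, 25 passed, 11 higher and 14 lower.

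The count of 46 became 12 without vector replicate 1, 3 without vector replicate 2, 162 without T158M replicate 1 and 174 without T158M replicate 2. The genes called in all 6 fits that left out 1 library were *PRM1*, *YGP1* and *YRO2*. Scaling on the library sizes behind the deposited CPM, chosen after seeing the data, left 5 genes, 4 higher and 1 lower, in place of 17 and 29. Without vector replicate 2 the calls ended for *HSP12* (adjusted p = 0.0786), *TMA10* (0.0645), *CIK1* (0.192), *YDR124W* and *YCR102C* (0.112 each), *PRY2* (0.353), *YHK8* (0.477), *RTC3* (0.193), *HXT7* (0.716), *SLX9* (0.436), *SPI1* (0.548) and *MET28* (0.246). Without vector replicate 1 the call of *VHR2* ended (adjusted p = 0.407).

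Of 26 general stress response genes 9 fell and 1 rose in total RNA of T158M against vector cells, and 13 fell and 1 rose adjusted over the list alone. *YGP1*, *TMA10* and *DDR2* (−1.48 ± 0.25) fell and *HSP12* rose, and the list median was −0.91 (camera adjusted p = 3.4e-13; adjusted p = 0.328 with an estimated correlation). Of 13 mating genes 4 rose and 0 fell, 6 rose adjusted over the list alone, and the median was 1.00 (camera adjusted p = 1.6e-12; adjusted p = 0.176 with an estimated correlation). Besides *PRM1* and *CIK1*, *AGA2* rose by 1.17 ± 0.22 and *STE2* by 1.00 ± 0.22. Of 33 respiration genes 2 fell, *COR1* (−0.93 ± 0.20) and *QCR7* (−0.82 ± 0.20), 12 fell adjusted over the list alone, and the median was −0.54 (camera adjusted p = 7.9e-11; adjusted p = 0.328 with an estimated correlation). Of 23 genes of the cytosolic chaperone list 1 rose, *HSP26* (0.81 ± 0.20), and 2 fell, the mitochondrial chaperone gene *HSP78* (−1.19 ± 0.30) and *SSA4* (−0.89 ± 0.23). Adjusted over the list alone 2 rose and 6 fell, and the median was −0.31 (camera adjusted p = 0.00215; adjusted p = 0.338 with an estimated correlation). Without vector replicate 2 the calls ended for *DDR2* (adjusted p = 0.295), *CIK1* (0.192), *AGA2* (0.489), *STE2* (0.563), *COR1* (0.539), *QCR7* (0.558), *HSP78* (0.563), *SSA4* (0.650, and in 4 further fits without 1 library), *TMA10* (0.0645) and *HSP12* (0.0786), and without vector replicate 1 for *HSP26* (0.592). The chaperone list did not pass without T158M replicate 2 (adjusted p = 0.133).

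Of 11 sulfur assimilation genes 2 fell in T158M against vector cells, *MET6* (−1.39 ± 0.25) and *MET28*, and 3 fell and 1 rose adjusted over the list alone. Their median was −0.44 (camera adjusted p = 0.00299; adjusted p = 0.338 with an estimated correlation). Of 130 ribosomal protein genes 0 passed in edgeR (9 at an unadjusted p under 0.05; 0 in DESeq2) and 0 adjusted over the list alone, while 106 lay below 0. Their median was −0.21 (camera adjusted p = 3.2e-05; adjusted p = 0.461 with an estimated correlation). Ribosome biogenesis genes lay higher: 0 of 48 passed in edgeR (6 at an unadjusted p under 0.05; 1 in DESeq2), 3 were higher adjusted over the list alone, and the median was 0.38 (camera adjusted p = 0.00247; adjusted p = 0.338 with an estimated correlation). For RNA polymerase I and III genes 0 of 16 passed in edgeR (1 at an unadjusted p under 0.05; 0 in DESeq2), 0 adjusted over the list alone, and the median was 0.39 (camera adjusted p = 0.0143; adjusted p = 0.328 with an estimated correlation). For the G2/M and M/G1 list 0 of 9 passed in edgeR (4 at an unadjusted p under 0.05; 0 in DESeq2), 3 were higher adjusted over the list alone, and the median was 0.55 (camera adjusted p = 0.0223; adjusted p = 0.338 with an estimated correlation). For glycolysis 0 of 14 passed in edgeR (3 at an unadjusted p under 0.05; 0 in DESeq2), 0 adjusted over the list alone, and the median was −0.22 (camera adjusted p = 0.0321; adjusted p = 0.338 with an estimated correlation).

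Some of these list calls of the T158M against vector comparison ended when a single library was left out, but those of ribosomal protein, general stress, mating and respiration genes did not. Without vector replicate 2, the adjusted p was 0.0550 for sulfur assimilation, 0.101 for ribosome biogenesis, 0.0915 for RNA polymerase I and III and 0.0886 for G2/M and M/G1. Without vector replicate 1 it was 0.122 for glycolysis and 0.443 for G2/M and M/G1, and without wild-type replicate 1 it was 0.139 for G2/M and M/G1. Without T158M replicate 1 it was 0.0926 for glycolysis and 0.0936 for G2/M and M/G1, and without T158M replicate 2 it was 0.133 for RNA polymerase I and III and 0.317 for G2/M and M/G1. The calls of *MET6* and *MET28* ended without vector replicate 2 (adjusted p = 0.200 and 0.246). Fry called 0 of the 23 lists in this comparison.

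With plasmids matched, stress genes were compared between wild-type MeCP2 and T158M in total RNA. Higher with wild-type MeCP2 were 14 of 26 general stress genes and 8 of 23 genes of the cytosolic chaperone list. The Hsp70 gene *SSA4* (YER103W, chromosome V, 366518 to 366645, plus strand) rose by 3.99 ± 0.23 (SE, n = 2 per group; adjusted p = 4.0e-11), *HSP26* by 3.16 ± 0.20 and *HSP12* by 2.85 ± 0.18. *SPI1* rose by 3.27 ± 0.34, *FMP16* by 3.23 ± 0.33, the catalase gene *CTT1* by 3.13 ± 0.58, *NCA3* by 3.32 ± 0.41 and *LOH1* by 2.86 ± 0.60. *CYS4* fell by 2.52 ± 0.34, *SVS1*, a cell wall gene, by 2.33 ± 0.37, the membrane stress protein gene *HSP30* by 2.19 ± 0.29 and the polyamine exporter gene *TPO4* by 2.16 ± 0.41. *RPS21A* fell by 2.10 ± 0.42, *COA2* by 1.95 ± 0.60 and *YDL124W* by 1.92 ± 0.61. The helicase gene *MAK5*, whose interval is only 7 bases long, fell by 3.14 ± 0.76. In edgeR 259 of 2447 genes passed, 127 higher and 132 lower (593 at an unadjusted p under 0.05; 149 in DESeq2).

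The count of 259 became 128 without vector replicate 1, 127 without vector replicate 2, 104 without wild-type replicate 1, 84 without wild-type replicate 2 and 551 without T158M replicate 1. Of the 259 genes, 45 were called in all 6 fits that left out 1 library, 33 higher and 12 lower. Scaling on the library sizes behind the deposited CPM, chosen after seeing the data, left 15, 13 higher and 2 lower, in place of 127 and 132. The T158M replicates differed most from each other. Their chi-square per degree of freedom was 7.92, against 2.52 for the vector and 2.57 for the wild-type replicates. The fit takes 1 spread per gene for all 3 groups, so it may understate that of T158M. When only the 4 libraries compared were fitted, 109 genes passed, 70 higher and 39 lower. Calls ended for *LOH1*, *COA2* and *YDL124W* without wild-type replicate 1 (adjusted p = 0.0602, 0.193 and 0.282) and for *MAK5* and *RPS21A* without T158M replicate 2 (0.194 and 0.121). The changes themselves then shrank, to −2.39 for *MAK5*, −0.68 for *RPS21A* and −1.74 for *CYS4*, while that of *CTT1* grew to 3.81. Without T158M replicate 1 that of *RPS21A* was −2.78. Without wild-type replicate 1 the changes were −4.11 for *MAK5* and 2.60 for *FMP16*, and without wild-type replicate 2 they were −2.54 for *MAK5*, −3.09 for *TPO4* and −2.59 for *YDL124W*.

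**Figure D2:**
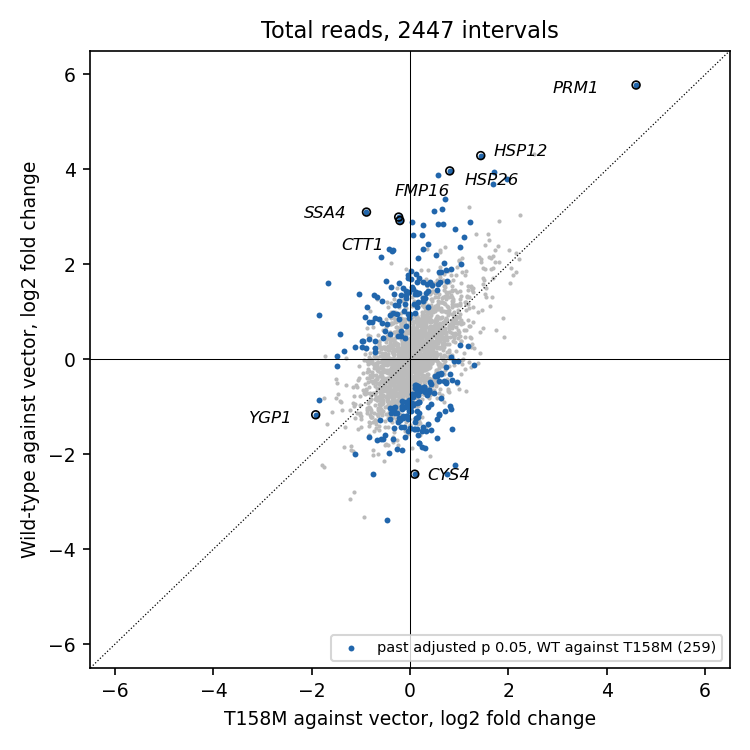
Log2 fold change of total reads in wild-type against vector cells (vertical) and in T158M against vector cells (horizontal) for 2447 intervals; blue points passed adjusted p 0.05 in wild-type against T158M (259), grey points did not, and the dotted line marks equal change. *SSA4*, *FMP16*, *CTT1*, *HSP26* and *HSP12* lie above that line and *CYS4* below it; both axes share the vector libraries.

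Of 26 general stress response genes 14 rose and 0 fell in wild-type against T158M cells, and 16 rose adjusted over the list alone. *HSP12*, *FMP16*, *SPI1* and *MSC1* (2.57 ± 0.37) were among them, and the median was 0.95 (camera adjusted p = 1.4e-16; adjusted p = 0.406 with an estimated correlation). Of 23 genes of the cytosolic chaperone list 8 rose and 1 fell, and 8 rose and 2 fell adjusted over the list alone. Their median was 0.21 (camera adjusted p = 1.1e-05, and adjusted p = 0.406 with an estimated correlation). Besides *SSA4* and *HSP26*, *SSA1* rose by 1.46 ± 0.19 and *SIS1* by 2.67 ± 0.43. Of 130 ribosomal protein genes 16 fell and 0 rose, 16 fell adjusted over the list alone, and the median was −0.30 (camera adjusted p = 3.2e-05; adjusted p = 0.586 with an estimated correlation). *RPL38* fell by 1.62 ± 0.26, *RPS27A* by 1.07 ± 0.21, *RPS21A* by 2.10 ± 0.42 and *RPS20* by 1.02 ± 0.21. Of 8 histone genes 4 fell and 0 rose, 5 fell adjusted over the list alone, and the median was −0.85 (camera adjusted p = 5.6e-04; adjusted p = 0.406 with an estimated correlation). They were *HTA2* (−1.11 ± 0.22), *HTB2* (−0.93 ± 0.20), *HHF1* (−1.41 ± 0.34) and *HTA1* (−0.71 ± 0.22). The calls of *RPS27A*, *RPS20*, *HTA2*, *HTB2* and *HTA1* ended without wild-type replicate 2 (adjusted p = 0.0896, 0.0814, 0.152, 0.0934 and 0.547), and those of *RPS21A* and *HHF1* without T158M replicate 2 (0.121 and 0.414), where their changes shrank to −0.68 and −0.35, that of *RPL38* shrank by over 1.5 times and that of *MSC1* grew to 3.71. Fry called 0 of the 23 lists in this comparison.

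**Figure D3:**
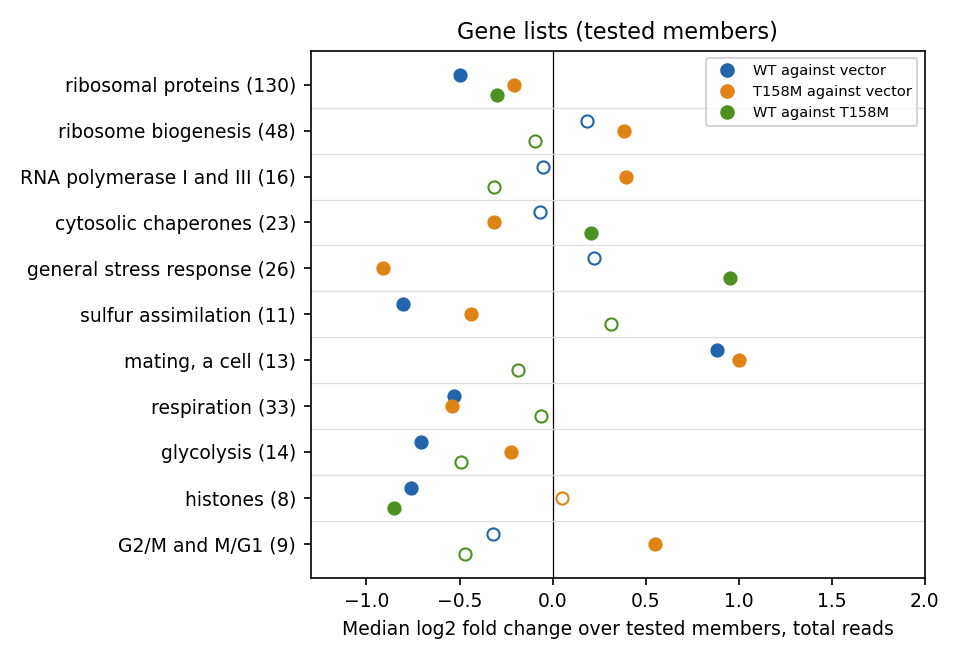
Median log2 fold change of total reads over the tested members (number in brackets) of 11 gene lists in the 3 comparisons; filled points passed camera's adjusted p of 0.05 with a preset correlation and open points did not. General stress genes had a median of −0.91 in T158M against vector cells and 0.95 in wild-type against T158M cells, and mating genes 0.89 and 1.00 in the comparisons with vector.

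The comparisons of wild-type and T158M cells with vector cells shared calls. In total RNA 14 genes were higher in both, against 1.46 for independent lists, and 21 were lower in both, against 2.68. The genes called in opposite directions were *SSA4*, with 3.10 ± 0.22 in wild-type and −0.89 ± 0.23 in T158M cells, and *SPI1*, with 1.61 ± 0.29 and −1.66 ± 0.36. The T158M calls behind this did not hold in all fits without 1 library. Such fits have fewer samples to estimate the spread, also where the library left out is not in the comparison. That of *SPI1* ended without vector replicate 2 (adjusted p = 0.548), and that of *SSA4* ended without vector replicates 1 and 2 (0.274 and 0.650), wild-type replicates 1 and 2 (0.113 and 0.109) and T158M replicate 2 (0.0923). The log2 changes correlated across genes at 0.550, against 0.502 simulated for unchanged groups with the same controls, and their covariance was 0.270, against 0.110 simulated. Unchanged groups shared 0 calls in the mean of 100 simulated draws. Such groups gave only 0.11 calls in total reads and 0.16 in T>C reads for wild-type against vector. Shared calls near 0 were thus set in advance in these draws, and the simulated numbers of shared calls do not test the overlap. In T>C reads 21 genes were lower in both, against 8.62 for independent lists and 0.0300 simulated, with a correlation of 0.531 (0.504 simulated) and a covariance of 0.355 (0.137 simulated). Genes are not independent replicates, and part of the excess may come from the shared controls, since the comparisons were not run with separate controls. The 35 genes shared in total RNA became 8 without vector replicate 1, 2 without vector replicate 2, 19 without wild-type replicate 1, 20 without wild-type replicate 2, 84 without T158M replicate 1 and 118 without T158M replicate 2. The 21 shared in T>C reads became 12 without vector replicate 2, and 0 with libraries scaled on T>C reads.

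The stress mRNAs that were high in total RNA of wild-type MeCP2 cells carried few T>C reads there. *HSP12* had 5 T>C reads of 13329 in wild-type cells, a share of 0.0375% (95% Wilson interval 0.0160 to 0.0878), against 22 of 744 in vector cells, 2.96% (1.96 to 4.44), and 3 of 2191 in T158M cells, 0.137% (0.0466 to 0.402). *HSP26* had 5 of 5568, 0.0898% (0.0384 to 0.210), against 25 of 391, 6.39% (4.37 to 9.27), and in T158M cells 10 of 747, 1.34% (0.729 to 2.45). *SSA4* had 11 of 2529, 0.435% (0.243 to 0.777), against 42 of 327, 12.8% (9.64 to 16.9), and in T158M cells 13 of 189, 6.88% (4.06 to 11.4). *SSA1* had 66 of 4527, 1.46% (1.15 to 1.85), against 304 of 2792, 10.9% (9.79 to 12.1), and in T158M cells 114 of 1921, 5.93% (4.96 to 7.08). These are sums over 2 libraries. Among genes tested for T>C reads, 28 were higher in total RNA of wild-type against vector cells, and 6 of these were lower in T>C reads (11.5 for independent lists). Of the 58 lower in total RNA, 38 were lower in T>C reads (23.8 for independent lists). T>C reads are part of the total reads of the same libraries, so such lists are not independent and these overlaps test nothing.

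**Figure D4:**
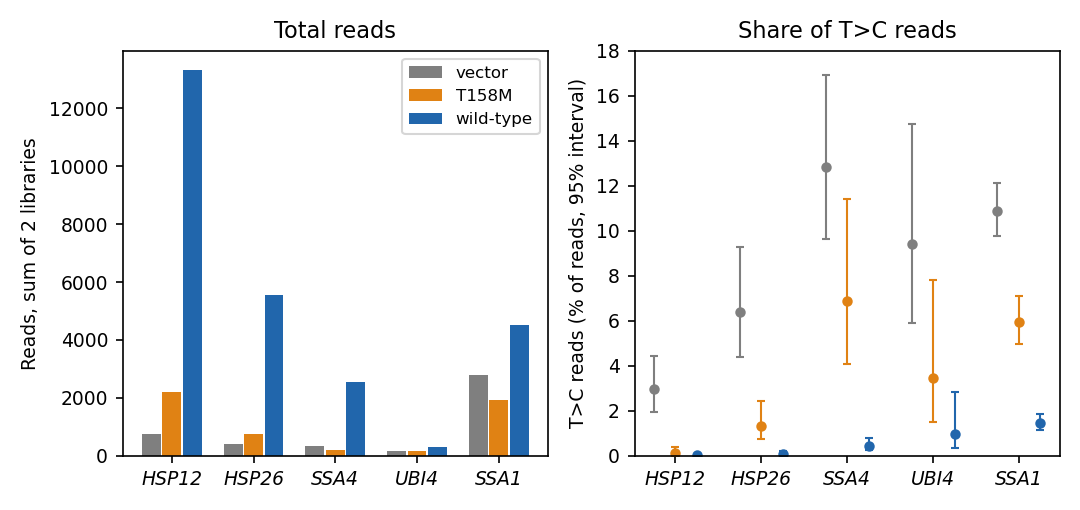
Total reads summed over 2 libraries (left) and percent of reads with T>C conversions with 95% Wilson intervals (right) for 5 stress genes in vector, T158M and wild-type cells. *HSP12* reads went from 744 in vector to 13329 in wild-type cells, while its T>C share went from 2.96% to 0.0375%; *UBI4* and *SSA1* were chosen after their values were seen.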

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

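All tests in this part were chosen only after the result was seen, and the rule that reads the test of strain differences was changed after its value was known.

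Multimapping reads, which no comparison used, were more frequent in both wild-type libraries and in T158M replicate 2 than in the control libraries. They made up 0.428% of interval reads in the wild-type libraries (mean), 0.348% in T158M replicate 1 and 0.536% in T158M replicate 2, against 0.335% ± 0.00373 (SD, n = 2) in the vector libraries. *PRM8*, the interval with the largest excess of such reads in wild-type over vector libraries, had 66 and 82 in the wild-type libraries, 22 and 30 in the vector libraries and 29 and 54 in the T158M libraries.

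The share of T>C reads in wild-type MeCP2 libraries was 0.491 of that in vector libraries. T>C reads did not carry fewer conversions, with 1.63 against 1.57 in vector libraries, 1.04 times as many. A density of label halved evenly over the new RNA would give 1.27, if conversions followed a Poisson distribution with 1 density. Whether they do was not tested, so a lower density spread unevenly over reads is not excluded. Reads added by the intervals called higher in total reads were excluded as the whole cause: over the 5319 other intervals the wild-type over vector ratio of the pooled share was still 0.533 (0.522 to 0.550 between single libraries). Over 263 intervals the median change was −1.17 for T>C against other reads, which older mRNA of most genes, built up before the pulse, could give, and −1.11 for T>C reads, which later uptake of 4-thiouracil, or uptake by fewer cells, could give. Both cannot be told apart from less transcription with MeCP2, which the design names, because the libraries hold no labelled spike-in.

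In wild-type cells 13 stress mRNAs were high in total reads, 6.43 times the vector level pooled, yet had few T>C reads; *HSP12* and *HSP26* gave most of the reads (13329 and 5568 of 27749), and *SSA1* most of the T>C reads (66 of 93, and 304 of 426 in vector libraries). T>C reads were countable in these intervals, at 9.04% of reads in vector libraries (95% interval 8.26 to 9.90). Pooled over these intervals, T>C reads were fewer than the overall lower share in wild-type libraries would give. The wild-type over vector ratio of their pooled T>C reads was 0.511 times that of all other intervals (95% interval 0.404 to 0.641). It was at most 0.806 between single libraries and 0.518 without *SSA1*, and a choice for high total reads would not lower it. The interval covers counting error only. The spread between genes was not tested, so a set of 13 intervals this low by that spread is not excluded. A candidate explanation is that these mRNAs were made before the pulse and kept, with less made during it: pooled T>C reads, scaled to library size, in wild-type cells were 0.238 (0.188 to 0.299; 0.241 without *SSA1*) of the vector level. In T158M libraries the 13 intervals took 0.734% of reads, against 0.666% in vector and 4.53% in wild-type libraries. Yet T>C reads were few there too, at 155 of 5465 (2.84%) against 426 of 4711 in vector libraries. Fewer T>C reads thus also occurred without such a rise in total reads. In vector libraries the T>C share was 9.04% against 3.98% in other intervals, and unusually many T>C reads there were not told apart. Since the genes were picked for high total reads and the uptake of label stays open, the explanation for wild-type cells is a hypothesis.

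In 19 intervals picked in the T158M libraries alone, with at least 10 reads and 50% T>C reads there, many reads carried conversions in the other libraries too, which T-to-C differences between the strain and the reference could give. Such differences would leave the share equal in all groups. The wild-type over vector ratio of the pooled share was 0.686 (95% interval 0.532 to 0.883), with 47.6% in vector and 32.6% in wild-type libraries. With 286 and 368 reads this leaves strain differences in part of these intervals open, and no biological explanation was tested. Single intervals, picked after their values were seen, differed. In vector, wild-type and T158M libraries, T>C reads were 10 of 10, 13 of 13 and 9 of 11 in *NTE1*. They were 6 of 6, 10 of 11 and 9 of 10 in *LYS5*, and 10 of 11, 13 of 19 and 10 of 11 in the marker *HIS3*. In *YGR127W* they were 11 of 30, 1 of 41 and 23 of 39. Together the 19 intervals held 0.479% of the T>C reads of vector and 0.998% of those of wild-type libraries.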

How the results depend on the processing

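The scaling on library sizes behind the deposited CPM and the exclusion of same-strand overlaps were chosen only after the results were seen. Of 165 named gene results, 0 reversed: the settings fixed beforehand left 1654 values on the same side of the threshold, 288 lost their call and 22 gained one, and the added ones left 255 and lost 72. Size factors of DESeq2 and the exclusion of same-strand overlaps moved no count of calls by over 1.5 times. Except where a setting tests fewer genes or samples, the cause was not tested. Leaving out a library leaves a group with 1 sample, which is then assumed to vary like the other groups. Such fits also have fewer residual degrees of freedom and test another set of genes. A lost call therefore does not show that the library left out carried the change. In T158M against vector, calls ended without vector replicate 2 although changes grew for *YDR124W* (2.21 to 2.41), *CIK1* (2.05 to 2.09) and *MET28* (−1.51 to −1.55). Depth limits T>C reads most: 263 genes passed the filter, and under 50 counts per library 20 did, so that no list of T>C reads had 5 tested members and that list test could not be run.

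Counts are given for wild-type against vector, T158M against vector and wild-type against T158M. For total reads (436, 46 and 259), the filter of 50 counts gave 247 in the first and 135 in the last, the 4 libraries compared 723, 25 and 109, the CPM library sizes 112, 5 and 15, and DESeq2 149 in the last. For T>C reads (108, 21 and 20), the filter of 50 counts gave 17, 9 and 11, scaling on the T>C reads 22, 0 and 5 (unadjusted p under 0.05 in edgeR: 62, 27 and 40), and conversions 61, 5 and 8. DESeq2 gave 13 in the second, no filter 13 in the last, the 4 libraries compared 32 and 11 and the CPM library sizes 9 and 11 in the second and the last. For T>C against other reads (98, 0 and 15), no filter gave 62, 1 and 9, the filter of 50 counts 19 and 14 in the first and the second, and own scaling of each kind of read 15 and 6 in the first and the last.

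The ratio of T>C shares of wild-type to vector libraries (0.491) was 0.452 as a median over intervals of 50 reads and 0.469 without ribosomal protein genes, and that of wild-type to T158M (0.693) was 0.628 as a median over intervals. Camera with an estimated correlation called 0 lists in each comparison of total and T>C reads, in place of 6, 10 and 4 and of 1, 1 and 0. Fry called 5 lists of total reads in wild-type against vector, 2 of them among the 6 of camera, 0 in T158M against vector and wild-type against T158M, and 4 of T>C reads in each comparison with vector. In T>C reads 234 of 263 genes lay below 0 in wild-type against vector and 220 in T158M against vector. The T>C calls of fry could follow from that common fall and say nothing particular about the lists. The overlap of T>C calls (21) was 12 in DESeq2 and 0 with scaling on the T>C reads.

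Leaving out 1 library gave 68 to 703, 3 to 174 and 84 to 551 calls for total reads, 79 to 153, 13 to 34 and 8 to 27 for T>C reads, and 34 to 89, 0 to 4 and 0 to 13 for T>C against other reads. List calls ranged from 5 to 7, 6 to 10 and 4 to 5 for total reads and from 0 to 5, 0 to 3 and 0 to 1 for T>C reads. The shared calls of the vector comparisons ranged from 2 to 118 in total reads and from 12 to 26 in T>C reads.

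Samples with the same replicate number did not all deviate together in total reads. The correlations of their deviations were −0.0308 for vector and wild-type, 0.175 for vector and T158M and −0.180 for wild-type and T158M. Replicates 1 and 2 had T>C shares of 3.88% and 4.10% in vector, 1.94% and 1.98% in wild-type and 2.69% and 2.96% in T158M libraries. Whether samples with the same number shared a batch is not in the labels and stays open. With a replicate block, T>C calls went to 11 in T158M against vector and 2 in wild-type against T158M, list calls of T>C reads to 2 in wild-type against vector and 1 in wild-type against T158M, and the overlap of T>C calls to 11. The block moved no other count by over 1.5 times (423, 44 and 228 for total reads).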

Other observations

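The oxidative stress, cell cycle, respiration and corepressor lists were picked for description after their values were seen, whereas the tests of turnover and abundance were set down before theirs.

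Genes of the oxidative stress response went both ways in total RNA of wild-type MeCP2 against vector cells: of 16 tested members 4 rose and 4 fell, with the same counts adjusted over the list alone. The NADPH oxidoreductase gene *OYE3* rose by 2.04 ± 0.23, the thioredoxin gene *TRX2* by 1.16 ± 0.20 and the glutathione transferase gene *GTT2* by 0.73 ± 0.17, while the mitochondrial superoxide dismutase gene *SOD2* fell by 1.15 ± 0.22 (SE, n = 2 per group). The list did not pass in camera (adjusted p = 0.489) but did in fry (adjusted p = 0.0391), and the calls of *GTT2* and *SOD2* ended without vector replicate 1 (adjusted p = 0.191) and vector replicate 2 (adjusted p = 0.0797), respectively. In wild-type against T158M cells 1 of 9 genes of the G2/M and M/G1 list rose and 3 fell, and 1 rose and 4 fell adjusted over the list alone. The cell separation genes moved apart: *DSE4* rose by 2.23 ± 0.37, and *DSE2*, *SCW11* and *DSE1* fell by 1.79 ± 0.29, 1.80 ± 0.39 and 1.13 ± 0.29. This list did not pass either (camera adjusted p = 0.178), and the call of *DSE1* ended without wild-type replicate 2 (adjusted p = 0.336). T>C reads of respiration genes were fewer in wild-type than in vector cells for 5 of 6 tested members, 6 adjusted over the list alone, beside 108 of all 263 genes, with a median of −2.15, but camera did not pass the list (adjusted p = 0.249). *SDH2* fell by 2.69 ± 0.56, *QCR9* by 2.01 ± 0.49, *ATP2* by 2.71 ± 0.77 and *COR1* by 2.12 ± 0.64. Without wild-type replicate 2 the changes became −2.04 for *SDH2* (−3.89 without wild-type replicate 1), −3.61 for *ATP2* and −2.86 for *COR1*. Their calls ended for *QCR9* without vector replicate 2 (adjusted p = 0.136, change −1.29) and for *ATP2* and *COR1* without wild-type replicate 1 (adjusted p = 0.0668 and 0.0893), and with libraries scaled on T>C reads none of the 4 passed (adjusted p = 0.0874, 0.297, 0.311 and 0.416).

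Genes of corepressors and histone deacetylases, the partners of MeCP2 in mammals, gave 0 calls of 9 in wild-type against vector cells in edgeR (1 at an unadjusted p under 0.05; 0 in DESeq2). All 9 lay above 0, with a median of 0.39, and the list did not pass (camera adjusted p = 0.390).

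Whether the fall of T>C reads in wild-type against vector cells differed by kind of gene was tested across the 263 tested intervals, as 2 relations with permutation tests of 100000 resamples. For turnover the T>C share in the T158M libraries was the stand-in. Spearman's rho with it was 0.206 (p = 8.3e-04, adjusted p = 8.3e-04, Pearson's r 0.294), opposite to a larger fall for mRNAs with a higher share. However, all 21 genes with fewer T>C reads in T158M against vector cells also had fewer in wild-type cells. Genes that fell in both would have a low share and a large fall, so this relation cannot decide on turnover. A larger fall for more abundant mRNAs may hold, with a rho of −0.218 with total CPM in the T158M libraries (p = 4.4e-04, adjusted p = 8.3e-04), though Pearson's r was −0.0504. Genes are not independent replicates, and the filter on T>C reads ties share and abundance together, so these are hypotheses.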
